A study of Capra hircus with 2 samples.

How the data were processed

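Testicular cells of 3 Saanen dairy goats were released with digestive enzymes, per the labels' protocols. A night of plating was meant to remove Sertoli and myoid cells, which attach, and the unattached cells were sorted magnetically into CD49f-positive and CD49f-negative cells. Small RNA libraries were made from total RNA with the Illumina TruSeq kit and sequenced on a GAIIx. The series text speaks of 3 repeats, but 2 samples are used here, 1 library per group, and whether goats were pooled is not stated. Each sample was placed in its group by its label.

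Per the file headers and the accompanying column description, the authors matched reads to mammalian miRNA hairpins in miRBase, to a goat genome and to expressed sequences. The aligner, miRBase release and genome build are not given in the sources used here. Coordinates are those of the deposited files, counted from 1. Interval lengths matched the listed hairpin sequence for 1352 of 1352 entries at known hairpins placed on the genome. The reads per hairpin arm are expected counts as the authors deposited them, with a read that fits several hairpins split between them and sequence variants with mismatches included. The number of copies of each listed sequence is a whole read count, per the file headers, repeated at each hairpin it fits. Hairpin GC content is a percent, per the file headers. No normalization was recorded for any of these values.

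The reads of entries with the same miRNA name and arm were summed within each library, without species prefix, for 1808 names. An entry without an arm in its name was given 1 arm from both libraries together, since the deposited arm label differed between the files for some entries. Unnamed entries, with 0.555% of listed reads in the CD49f-positive library and 0.611% in the CD49f-negative library, stayed out of the totals and comparisons. No mismatch was found in 67.0% and 63.7% of listed reads. Ratios are shares of named miRNA reads, positive over negative, with 0.5 reads added to each count. Their 95% intervals are exact conditional binomial (Clopper-Pearson) intervals of the expected counts rounded to whole reads, and they cover counting error only. A miRNA was called higher or lower with at least 100 summed reads, a ratio of at least 2-fold and an interval that excludes 1. A count of 0 was given a floor of 3 reads.

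The size rule, lists, named miRNAs and most alternatives were fixed before the data were examined. Named were the 10 most abundant miRNAs of each library, the 12 highest and 12 lowest ratios that met the size rule, miRNAs with at least 100 reads in 1 library and 0 in the other, and at most 4 further members of each of 22 lists. Only 6 miRNAs met the rule for higher ratios. let-7a-3p, let-7b-3p, miR-181c-3p and further members named as exceptions were chosen after their values were seen. A list with at least 3 measured arms was given the percentile of its median among 10000 random lists of the same size, drawn from the 20 miRNAs nearest in mean expression to each member; 19 lists had one. These percentiles describe these 2 libraries. Each arm was swapped on its own, although arms of 1 hairpin or of neighbouring hairpins are not independent. This can make a percentile more extreme, so it is no measure of probability.

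The alternatives were TMM scaling with edgeR 4.0.16, median-of-ratios size factors with DESeq2 1.42.0, a total without the 10 most abundant miRNAs, other read minimums, a 4-fold rule, a prior of 5 reads, the most abundant sequence alone, and narrower sets of names or reads. Both tools supplied scaling factors only, in R 4.3.3. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Calling was tested on Poisson counts simulated for the 1808 names of this comparison. Of miRNAs changed 3-fold, 22 of 22 were called, as were 0 of 269 unchanged ones. Intervals held the true value for 90.9% of miRNAs changed 3-fold, 90% of those changed 1.5-fold and 94.1% of unchanged ones. Poisson counts vary by counting error only, which the intervals assume. The simulation therefore checks the calculation and gives no rate of false calls between real libraries. None of 20 miRNAs changed 1.5-fold was called, since the rule asks for 2-fold.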

Results

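MicroRNAs (miRNAs), short RNAs that repress messenger RNAs by base pairing, were sequenced from testicular cells of Saanen dairy goats aged 5 months. The cells came from 3 testes of 3 goats and were sorted magnetically by CD49f, the integrin alpha-6 chain, a surface protein used to enrich spermatogonial stem cells. The comparison asks which miRNAs differ between CD49f-positive and CD49f-negative cells. Each group had 1 library, so no difference has a replicate check and no p-value is given. The CD49f-positive list held 8196507 reads assigned to named miRNAs and the CD49f-negative list 3064462, which makes the positive library 2.67 times deeper. These totals cover miRNA-matched reads only. They fell under 1455 and 1291 miRNA names, and 98.4% and 97.8% of all listed reads lay at known miRNA hairpins placed on the goat genome.

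The same few miRNAs filled both libraries. miR-100-5p took 25.4% of the reads in each as the authors split shared reads, and miR-143-3p, abundant in smooth muscle and other mesenchymal cells, took 22.1% of the CD49f-positive reads (95% interval 22.1 to 22.2) and 18.4% of the CD49f-negative reads (18.4 to 18.5). miR-10b-5p, encoded in a HOX gene cluster, made up 13.6% and 7.55%, and miR-99a-5p 12.3% and 10.2%. miR-34c-5p, abundant in meiotic and post-meiotic male germ cells, stood apart with 2.13% of the CD49f-positive reads (2.12 to 2.14) and 10.9% of the CD49f-negative reads (10.8 to 10.9). miR-26a-5p held 1.66% and 1.68%, and miR-21-5p 1.56% and 2.14%. The CD49f-positive top 10 was completed by let-7f-5p (1.39%), let-7a-5p (1.33%) and miR-126-3p (1.32%). The CD49f-negative top 10 was completed by miR-148a-3p (1.22%), miR-101-3p (0.980%) and miR-99b-5p (0.952%). The 10 most abundant miRNAs held 82.8% and 79.4% of the reads, and 7 names stood in both top 10 lists. Intervals are exact Clopper-Pearson intervals and cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

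miR-99a-5p and miR-100-5p could not be separated fully. The sequence AACCCGTAGATCCGATCTTGT, listed with 0 mismatches for miR-99a-5p and 1 for miR-100-5p, had 1561262 copies in the CD49f-positive library and 398781 in the CD49f-negative library, and its reads were shared between both names. All of its copies were then given to miR-99a-5p, on the assumption that the authors had split them equally between both names. On that assumption miR-99a-5p held 21.9% of the CD49f-positive and 16.7% of the CD49f-negative reads. miR-100-5p held 15.9% and 18.9%, so their order in the CD49f-positive library turned. The log2 ratio of CD49f-positive over CD49f-negative was then 0.39 for miR-99a-5p and -0.25 for miR-100-5p. Both miRNAs together took 37.8% and 35.6% of the reads.

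Of 298 miRNAs with at least 100 reads summed over the libraries, 74 were at least 2-fold lower and 6 at least 2-fold higher in CD49f-positive cells, with an interval that excluded equal shares. The other 218 met no such rule. Of these calls, 24 lower and 4 higher ones were of miRNAs with under 50% of their reads at known hairpins, which left 50 lower and 2 higher. The split depends on how the libraries are scaled. TMM scaling, which is less sensitive to the few dominant miRNAs, raised every log2 ratio by 0.45 and gave 40 lower and 27 higher miRNAs, so a ratio below 1 by less than that shift changes direction. All 40 of these lower miRNAs and all 6 higher ones of the read-total scaling were called under both. Among miRNAs at known hairpins TMM gave 26 lower and 22 higher. Median-of-ratios scaling raised log2 ratios by 0.60 and gave 28 lower and 34 higher miRNAs. Leaving the 10 most abundant miRNAs out of the total raised them by 0.31 and gave 16 higher miRNAs. Calls higher made up 7.5% of all calls with the read total, 40.3% with TMM, 54.8% with the median of ratios and 23.5% without the 10 most abundant. The median log2 ratio of all 298 miRNAs was -0.43 with the read total and 0.02 with TMM. A group's position among the other miRNAs is therefore given beside its median.

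**Figure D1:**
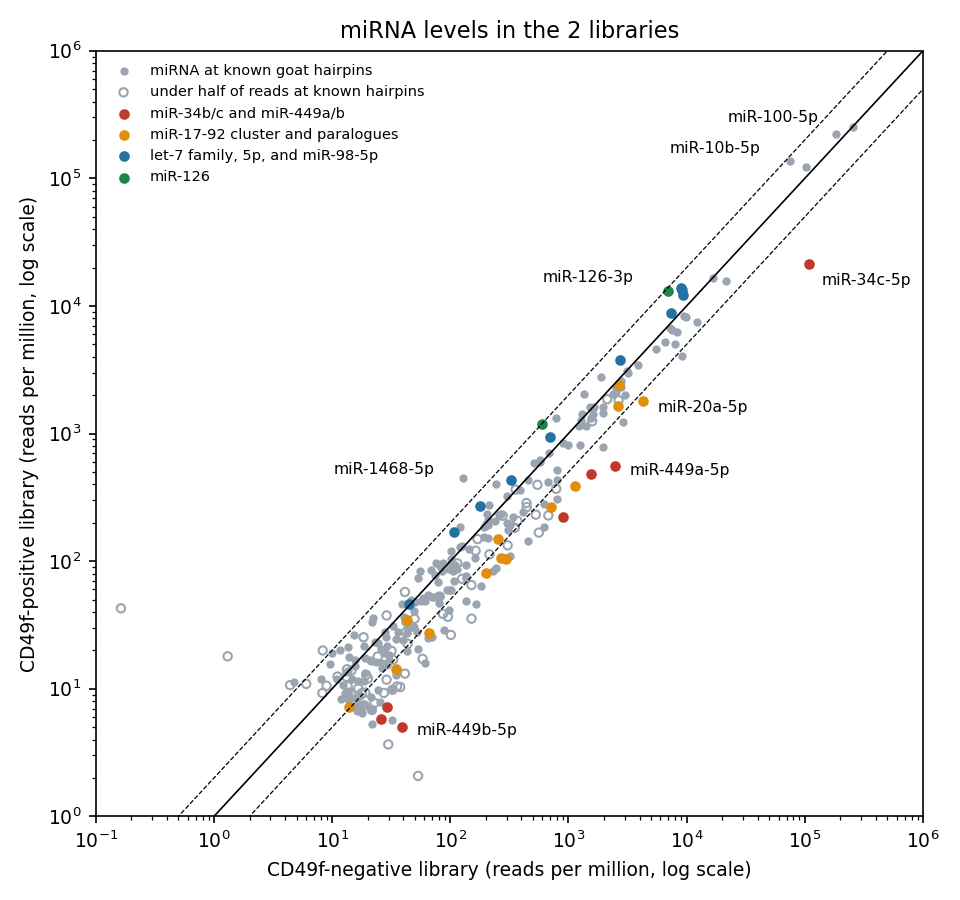
Named miRNA reads, scaled to 1000000 per library, in the CD49f-negative library (x axis, log scale) and the CD49f-positive library (y axis, log scale) for 298 miRNAs with at least 100 summed reads, with 0.5 reads added to each. The solid line marks equal shares and the dashed lines 2-fold differences; colours mark miRNA groups and open circles mark miRNAs with under 50% of their reads at known hairpins. miR-34c-5p (2.13% of CD49f-positive and 10.9% of CD49f-negative reads) lies furthest from the line among the abundant miRNAs.

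The miR-34b/c and miR-449 miRNAs, families that share a seed sequence and are abundant in meiotic and post-meiotic germ cells, were lower in CD49f-positive cells. miR-34c-5p was 5.11 times lower (log2 ratio -2.35, 95% interval -2.36 to -2.35). Its hairpin lies on chromosome 15 at 20049309 to 20049410, beside that of miR-34b at 20048589 to 20048694. miR-34b-5p had a log2 ratio of -2.00 (-2.09 to -1.92), miR-34b-3p one of -1.69 (-1.75 to -1.63) and miR-34c-3p one of -2.02 (-2.52 to -1.53). The miR-449a hairpin, on chromosome 20 at 23893130 to 23893217, gave miR-449a-5p at -2.18 (-2.23 to -2.12) and miR-449a-3p at -2.16 (-2.72 to -1.63). miR-449b-5p, from 23893006 to 23893102, had 40.5 and 120 reads and a log2 ratio of -2.97 (-3.52 to -2.45). Only 4.5 and 8.5 of these reads had no mismatch, with a log2 ratio of -2.34 (-4.27 to -0.61), and the most abundant sequence alone gave -3.65. Over reads with no mismatch miR-449b-5p, miR-34c-3p (34 and 51 reads) and miR-449a-3p (28 and 47) fell under the minimum of 100 reads, which ends their calls, while the ratios of miR-34c-3p and miR-449a-3p were -2.07 and -2.23. The list of meiotic and post-meiotic miRNAs had 14 measured arms, all with ratios below 1, of which 8 met the 2-fold rule, or 7 with TMM. Under TMM scaling the 4 arms of miR-24 and miR-191 turned above 1, among them miR-24-3p from -0.09 to 0.35 and miR-191-5p from -0.39 to 0.06. The list's median was -1.49, or -1.05 with TMM, at percentile 0.02 of 10000 random lists matched on expression. Its miR-34 and miR-449 arms come from neighbouring hairpins on chromosomes 15 and 20 but were drawn as separate members, which can make the percentile more extreme. Over reads with no mismatch the list's median was -0.88, with 10 arms measured. The list of p53-responsive miRNAs had a median of -1.24 at percentile 1.04, with 6 of 9 arms lower, or 4 lower and 1 higher with TMM, but 4 of its arms belong to miR-34b and miR-34c.

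The miR-17-92 cluster and its paralogues, miRNAs of proliferating cells, were also lower in CD49f-positive cells. All 13 measured arms had ratios below 1, although those of miR-92a-3p and miR-92b-3p turned above 1 with TMM. The 2-fold rule was met by 8 arms with the read total and by 2, miR-17-5p and miR-93-5p, with TMM. miR-17-5p and miR-106a-5p shared a listed sequence with 665 copies in each library, at 1 and 2 mismatches, so these arms are not independent. miR-20a-5p had a log2 ratio of -1.24 (-1.28 to -1.21), or -0.80 with TMM, and miR-93-5p, with 3203 and 3507 reads, one of -1.55. miR-25-3p, at -0.68, and miR-92a-3p, at -0.17, did not reach 2-fold. The group's median was -1.26, or -0.82 with TMM and -0.67 with the median of ratios, at percentile 0.235, with arms of neighbouring hairpins drawn as separate members.

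Other miRNAs among the 12 lowest ratios belonged to no germ cell list. miR-331-3p had a log2 ratio of -2.49, miR-6123-5p one of -2.03 and miR-32-5p one of -1.94. Over reads with no mismatch miR-331-3p (26 and 41 reads) and miR-6123-5p (33 and 43) also fell under the minimum, with ratios of -2.14 and -1.87. miR-375-3p, at -2.09 with 290 and 463 reads, was matched to a hairpin not placed on the goat genome. miR-716a-5p (-4.69) and miR-339-5p (-3.03) had 14.5% and 0% of their reads at known hairpins. miR-716a-5p had 16.5 and 163 reads, while the like-named miR-716b-5p, among the higher miRNAs below, had 146.5 and 3.5. Their 3p arms were alike, at -0.61 and -0.54. Whether the 5p reads of both names can be told apart was not tested, so these opposite ratios may not be separate differences. Of miR-339-5p's reads 0.5 in each library had no mismatch, so its difference rests on mismatched reads. The like-named miR-339b-5p, with 1868.5 and 2069 reads, had a log2 ratio of -1.57.

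Among the 6 miRNAs higher in CD49f-positive cells, miR-1468-5p had the most reads. It had 3656 and 390 reads, a log2 ratio of 1.81 (1.66 to 1.96) and a hairpin on chromosome X at 83737311 to 83737404. miR-29a-5p had a log2 ratio of 1.25 from 92 and 14 reads, part of which lay at a locus named miR-29c in the CD49f-negative list, and over its 65 and 14 reads with no mismatch the log2 ratio was 0.68 (-0.13 to 1.67), which ends the call. The remaining 4 had under 50% of their reads at known hairpins. miR-1290-3p had 349.5 reads in the CD49f-positive library and 0 in the CD49f-negative one, at least 43.6-fold higher against a floor of 3 reads. The lower end of its exact 95% interval was 35.3-fold. miR-716b-5p had a log2 ratio of 3.78, opposite to miR-716a-5p at -4.69, miR-940-5p one of 1.28 and miR-450a-3p one of 1.26. Over reads with no mismatch miR-450a-3p had 19 and 5 reads and a log2 ratio of 0.33 (-1.04 to 2.21), and miR-716b-5p had 19 and 0 reads, under the minimum of 100 in both cases.

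The let-7 family, miRNAs of differentiated cells that target growth regulators, was high in CD49f-positive cells relative to other miRNAs. No arm reached 2-fold with the read total, while let-7d-5p (1.08), let-7f-5p (1.07) and miR-98-5p (1.04) did with TMM. let-7f-5p had a log2 ratio of 0.62 (0.61 to 0.64), let-7a-5p 0.53 (0.51 to 0.55), let-7g-5p 0.38 and let-7i-5p 0.27. Ratios were above 1 for 9 of 11 arms, and let-7a-3p and let-7b-3p were the exceptions at -0.24 and -0.08, both above 1 with TMM. The median of 0.42, or 0.86 with TMM, lay at percentile 99.8. Several 5p arms have fractional counts, because reads that fit several hairpins were split between them. These arms are therefore not independent, which can make the percentile more extreme. let-7f-5p and miR-98-5p also count among the chromosome X arms examined below. The miR-181 family had a median of 0.21 at percentile 98.9 over 6 arms, of which none was called with the read total and 2 were higher with TMM, with miR-181a-5p at 0.76 and miR-181c-3p at -0.75.

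The endothelial list was high as well, with 3 measured arms. miR-126-3p had 107917 and 21312 reads and a log2 ratio of 0.92 (0.90 to 0.94), miR-126-5p one of 0.99 and miR-139-5p one of 0.46. The median of 0.92 was at percentile 99.9 and was 1.37 with TMM, which puts both miR-126 arms past 2-fold. That median is the value of miR-126-3p, and the percentile counts both arms of the miR-126 hairpin. miR-139-5p had 207 and 56 reads, 0% of them at known hairpins. The result thus rests mainly on 1 hairpin. The X-linked clusters outside the miR-506 family had a median of 0.04 at percentile 99.97, with 1 of 29 arms higher and 2 lower. The higher arm was miR-450a-3p, which had no call over reads with no mismatch. With TMM 8 arms were higher and none was lower. miR-542-3p had a log2 ratio of -0.11, miR-450b-5p 0.58, miR-450a-5p 0.14 and miR-424-5p 0.04. This median was -0.095 over 43 arms with at least 10 reads and 0.48 with TMM, so its sign depends on the filter.

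miRNAs that rodent studies tie to undifferentiated spermatogonia went both ways. Of 20 measured arms, 8 were lower, none was higher, and the median of -0.68 (-0.24 with TMM) lay at percentile 6.93. With TMM 3 arms were lower (miR-34c-5p, miR-34c-3p and miR-31-5p) and 3 higher (miR-10b-5p, miR-224-5p and miR-221-5p). miR-10b-5p had a log2 ratio of 0.85 (0.84 to 0.85), miR-21-5p -0.45, miR-146b-5p -1.30 (-1.35 to -1.25), and miR-204-5p -0.89. miR-21-5p was near equal shares with TMM, at -0.01, and above 1 with the median of ratios, at 0.15. The list shares miR-34c with the meiotic list, miR-20a and miR-106a with the miR-17-92 list, and miR-221, miR-222, miR-224 and miR-424 with the X-linked clusters. It also shares miR-21, miR-31, miR-146a and miR-146b with the culture and stress list and miR-10b with the HOX-cluster list.

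Lists for other cell types gave medians from -0.71 to -0.15. Of 4 Sertoli arms, miR-202-5p was lower, at -1.38 (-1.46 to -1.30), a call lost with TMM, and miR-125a-5p was at -0.03; the median was -0.59, above 0 with the median of ratios, at percentile 36.7. The myoid, smooth muscle and fibroblast list had a median of -0.15 over 16 arms, at percentile 91.7, and turned to 0.30 with TMM. In it miR-143-3p had a log2 ratio of 0.26, miR-199b-5p -0.19 and miR-145-3p 0.56 against -1.24 for miR-145-5p. Of its 16 arms 1 was higher and 3 were lower, or 2 higher and 0 lower with TMM. The higher arm with the read total was miR-29a-5p, whose call ended over reads with no mismatch. With TMM miR-145-3p gained a call at 1.01 and miR-145-5p lost one at -0.79. Red blood cell miRNAs had a median of -0.35 (0.10 with TMM) and percentile 32.3, with miR-451-5p at -0.29. White blood cell miRNAs had a median of -0.71 and percentile 27.6, with miR-342-3p at -0.70 and miR-155-5p at 0.59, or 1.04 and past 2-fold with TMM. The epithelial list had 1 measured arm, miR-200b-3p, which was lower at -1.62. Neither the pluripotent stem cell list nor the miR-506 family had an arm with at least 100 reads.

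**Figure D2:**
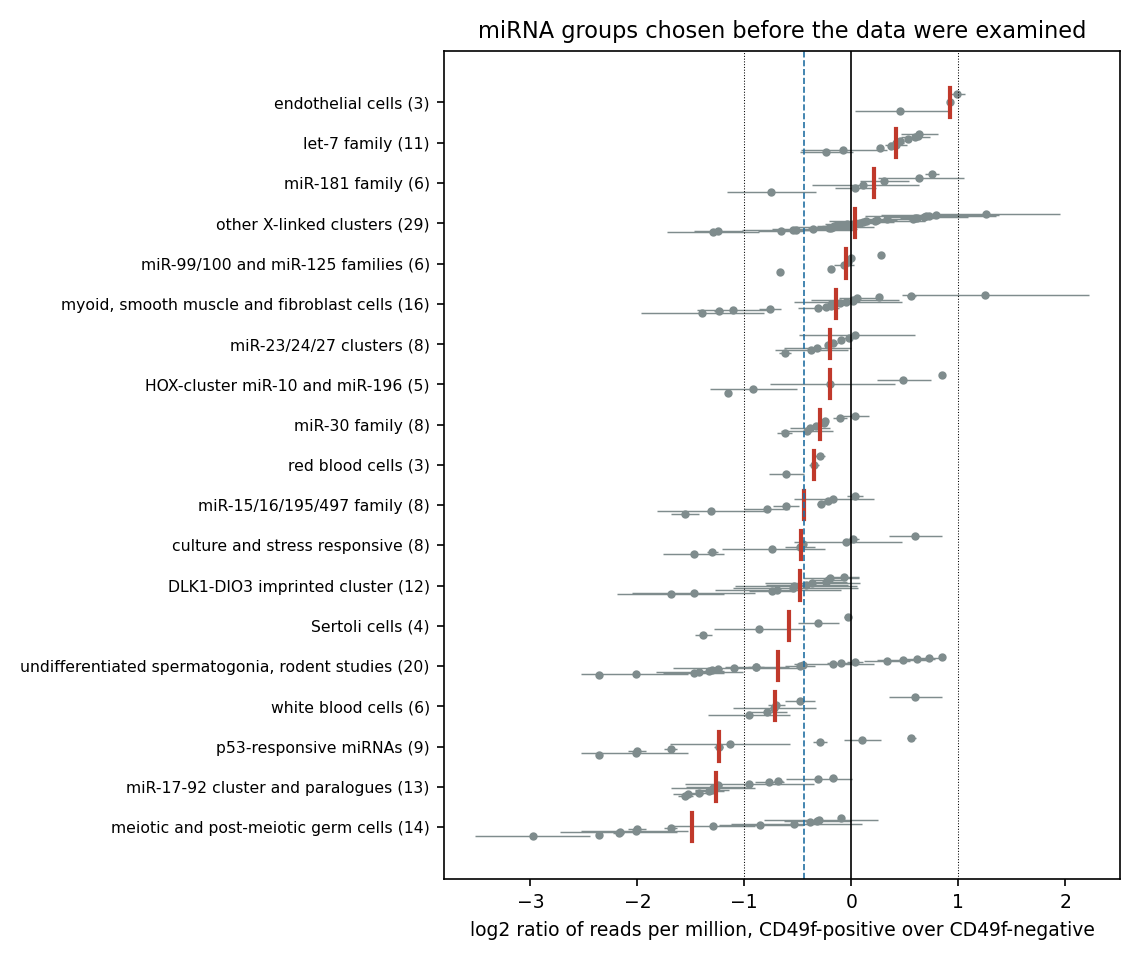
Log2 ratios of read shares, CD49f-positive over CD49f-negative (x axis), for the measured arms of 19 miRNA lists (y axis, number of arms in brackets). Grey points are arms with 95% counting intervals, red bars are list medians, dotted lines mark 2-fold, and the dashed blue line marks equal levels under TMM scaling. Medians run from -1.49 for meiotic and post-meiotic miRNAs to 0.92 for endothelial ones, and medians between the dashed line and 0 change direction under TMM.

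The remaining lists lay within the middle of the random lists. The HOX-cluster miRNAs had a median of -0.20 (0.25 with TMM) at percentile 78.0, and miR-10a-5p, at -1.15 (-1.17 to -1.13) or -0.70 and under 2-fold with TMM, went the other way from miR-10b-5p. The miR-99/100 and miR-125 families had a median of -0.05 (0.39 with TMM) at percentile 76.7, and miR-125b-5p was at -0.67. The DLK1-DIO3 imprinted cluster had a median of -0.48 (0.12 with the median of ratios) at percentile 72.6, with 2 of 12 arms lower. The miR-15/16 family had one of -0.45 (0.15 with the median of ratios) at percentile 36.7, with 2 of 8 arms lower, or 1 with TMM, and miR-16b-5p at -0.28. The miR-30 family had a median of -0.29 (0.15 with TMM) at percentile 39.8, and the miR-23/24/27 clusters one of -0.19 (0.25 with TMM) at percentile 68.0. The list of miRNAs responsive to culture and stress had a median of -0.47, above 0 with the median of ratios, at percentile 30, with 2 of 8 arms lower, or 1 lower and 1 higher with TMM.

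The pooled length distribution of the listed sequences differed between the libraries. Sequences of 22 bases held 48.2% of the copies of listed sequences in CD49f-positive cells and 23.6% in CD49f-negative cells, and those of 23 bases 6.27% and 22.3%. The files list 1 representative sequence per hairpin arm, not all reads. For miR-143-3p it was TGAGATGAAGCACTGTAGCTCT in the CD49f-positive library, with 649830 copies, and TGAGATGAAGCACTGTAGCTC in the CD49f-negative one, with 215703. Without these, 22-base sequences held 38.5% and 27.9%, and 23-base sequences 7.44% and 26.4%. Other abundant miRNAs, among them miR-34c-5p, were kept, so the remaining gaps can follow their unequal shares and need not be differences in length. Sequences of 21 bases held 41.7% and 49.5% with them and 49.6% and 40.3% without, so their order turned. The sequence shared by miR-99a-5p and miR-100-5p, which was kept, had 1561262 of 1716977 CD49f-positive and 398781 of 691635 CD49f-negative copies of 21 bases. That order therefore depends on which abundant sequences are counted. A first base of T was found in 53.6% and 47.1% of copies. The listed miR-143-3p sequences begin with T, and the sequence shared by miR-99a-5p and miR-100-5p begins with A. First-base shares can therefore also follow the unequal shares of abundant miRNAs and need not be differences in the ends of the reads.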

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

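The tests in this part were chosen after the result was seen. Reads in entries with no miRNA name lie outside the comparison, and numbered 45707 in the CD49f-positive library and 18827 in the CD49f-negative library, above the 3 reads that a count of 0 allows. Most belonged to 1 sequence, TAGCAGCACGTAAATATTGGAGA, with 38387 and 14577 reads.

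This sequence was placed on chromosome 12 from 18444407 to 18444669, minus strand, across the hairpin of miR-16a at 18444474 to 18444562. It begins with all 22 bases of the goat miR-16a sequence listed at that hairpin (the first 20 match the known cow miR-16a), followed by 1 more base, so it may be a 3' variant of miR-16 that was given an entry of its own. miR-16 reads would then be undercounted in both libraries, about alike, since the log2 ratio of the sequence was -0.02 (-0.05 to 0.01). A further miRNA gene at the locus cannot be told apart: 0.0151% of its reads matched with no mismatch, but per the file headers the entry holds only reads not matched to known hairpins; no biological explanation was tested.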

How the results depend on the processing

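Calls higher and lower were 27 and 40 with TMM and 34 and 28 with the median of ratios, against 6 and 74, and 16 were higher without the 10 most abundant miRNAs; the shifts of 0.45, 0.60 and 0.31 are the same for every miRNA and cause these moves. With at least 10 reads 10 were higher and 159 lower of 592 miRNAs, with at least 1000 reads 1 and 26 of 140, with no minimum 10 and 196 of 1808, and under the 4-fold rule 2 and 11; these follow from the number of miRNAs tested or the stricter rule. The most abundant sequence alone gave 35 lower of 184 miRNAs, and fewer miRNAs entered. Known hairpins alone, chosen after seeing the data, gave 2 higher of 228. The median of the other X-linked clusters reversed to -0.095 over 43 arms with at least 10 reads; more arms entered. TMM moved the medians of let-7 to 0.86, endothelial to 1.37, red blood to 0.10, miR-99/100 and miR-125 to 0.39, miR-30 to 0.15 and miR-23/24/27 to 0.25. The median of ratios moved these to 1.02, 1.52, 0.25, 0.55, 0.31 and 0.41, miR-17-92 to -0.67, other X-linked to 0.63, white blood to -0.11, DLK1-DIO3 to 0.12, miR-15/16 to 0.15 and miR-181 to 0.81. Without the 10 most abundant, let-7 moved to 0.73, endothelial to 1.23, red blood to -0.040, miR-30 to 0.016 and miR-23/24/27 to 0.11. The other 105 list values moved by no more than the standard deviation among their list's members, and the other 11 counts stayed within 1.5 times. That spread is no error of the median, and some of these values changed sign. With TMM and the median of ratios the myoid list went to 0.30 and 0.45 and the HOX-cluster list to 0.25 and 0.40. With the median of ratios the Sertoli list went to 0.01 and the culture and stress list to 0.13. Of 140 values for single named miRNAs, 88 moved beyond their counting interval and 52 did not. The 4 values for lengths and first bases held with sequences seen at least 10 times, but rarer sequences hold too few copies to move them. Leaving out miR-143-3p moved the 22-base shares to 38.5% and 27.9%. No paired analysis was possible because each group has 1 library; for the same reason none could be left out. Depth limits miRNAs near 100 reads, whose intervals span over 2-fold.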

Other observations

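The tests of the miR-34 with miR-449 and chromosome X patterns in this part were chosen after the results were seen. Of 47 miRNAs with both arms measured at known hairpins, 40 had log2 ratios of the arms within 2-fold of each other, against a mean of 28.3 when arms of different hairpins were paired at random. The arms had the same direction in 30 and opposite directions in 17, against 27.5 with the same direction in random pairs, and the log2 ratios of the arms had a Pearson r of 0.62 across miRNAs, which are not independent replicates. Exceptions, named after their values were seen, included miR-145, with the 3p arm at 0.56 and the 5p arm at -1.24, and miR-331, with the 5p arm at 0.05 and the 3p arm at -2.49. The end of the library kit's 5' adapter, CTACAGTCCGACGATC, was listed with 1214 copies in the CD49f-positive library and was not among the sequences listed for the CD49f-negative library.

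The 7 arms of miR-34b, miR-34c and miR-449 had a median log2 ratio of -2.16. The highest median over the other 3 scalings was -1.56, so none of them brought it within 2-fold. Each scaling adds 1 constant to every log2 ratio, so this follows from the known shifts and is no separate test of scaling. Mismatched reads are argued against, since the median of these arms was -2.10 over reads with no mismatch. Fewer meiotic and post-meiotic germ cells in the CD49f-positive library remain a candidate explanation: the other 7 arms of that list had a median of -0.39 at percentile 59.6, which lies above the bound of 50 first set against this explanation. That bound was set aside after the value was seen, because 1 of these arms has at least 1000 reads and stands in no other list, where 3 were then asked for; read by the bound as first set, the test argues against this explanation. A difference in expression between CD49f-positive and CD49f-negative cells of the same type is also open and was not tested.

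The 34 measured arms from chromosome X hairpins had a median log2 ratio of 0.06, against -0.42 for the other arms at known hairpins, and 52.9% against 22.1% had ratios above 1. This placed them at percentile 99.98 of lists matched on expression, with arms of 1 hairpin or cluster drawn as separate members. The percentile was 99.96 with hairpin GC also matched, although the median hairpin GC was 43.5% against 51.7%. Matching on hairpin GC thus hardly changed it. The GC content of the sequenced arms was not matched, and linked arms were again drawn separately, so GC content cannot be excluded as a cause. A single cluster is argued against as the whole cause too, since without 9 arms between 24347251 and 24354088 the percentile was 99.11, although the median then turned to -0.042. A difference between the sorted cells themselves stays open as a hypothesis and was not tested, since each group has 1 library.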
